A study of Homo sapiens with 27 samples.

How the data were processed

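Total RNA of HuES6 cells, an established human embryonic stem cell line, was amplified, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The set held 27 arrays, 13 of time course 1 and 14 of time course 2. The labels give no number for the IWP-2 dose, and say of 2 arrays, IWP-2 on days 3 and 6 of time course 1, that they are also part of another series. The scanner table as deposited holds, per the file headers, 1 signal intensity and 1 detection p-value per probe and array, and GenomeStudio is named in the submitters' processing notes without a version. These intensities were neither background subtracted nor normalized, judged from the values. Detection columns share 1 header name, and each was paired with the signal column to its left, whose order it follows without exception. The authors' processed intensity values are a second table on a linear scale, each column rising with the same array's scanner signal (rank correlation 1). Their medians are 6.876 in every array of time course 1 and 4.630 in every array of time course 2, so they look normalized within each time course, and the method is not given in the sources used here. They served as an alternative only.

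Of 47323 probes, 30113 carried 1 gene symbol in the annotation given, 8 several and 17202 were not listed there and are unnamed here. Entrez identifiers of 30074 probes matched the RefSeq gene table, and no symbol changed. Intensities were background corrected and quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with the normexp background taken from the detection p-values and an offset of 16, and taken to log2. Probes detected at a p-value below 0.01 on at least 2 arrays were kept (23933, of them 18435 with 1 gene), and the probe with the highest mean stood for its gene, which left 13572 genes. For 3820 genes more than 1 probe was detected, and probes that missed the test or differed in sign are given beside the named genes. Other probes of a gene could pass with a smaller difference. Quantile normalization gives every array the same highest value, 14.17, so differences of the brightest probes may be understated.

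Linear models were fitted to all 27 arrays with limma's lmFit and eBayes, with 1 mean per day and arm and the time course as a block, and p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. The inhibitor arms of both time courses formed 1 arm. The block was part of the design because the labels name each arm without inhibitor as the control of its own time course. The 13 groups with 2 arrays deviated together, with correlations of the time course difference between 0.122 and 0.802, over 0.1 in 78 of 78 pairs of groups. Differences are log2 with their standard error (SE). Where a gene was not above background on any array of a group, the fold is a lower bound, computed from the brighter group's mean against the mean over the dim group's arrays of the higher of the lowest detected value and the probe's own value. Of 464 genes on 22 lists, 430 had a named probe and 383 were tested. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative. TNNT2 is not analysed here.

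The comparisons, the lists and all but 2 of the alternatives were fixed before the data were examined. Named genes were, per comparison, the 8 largest positive and 8 largest negative differences among genes that passed with the same sign in both time courses, up to 4 passing members of each list described, and a set of fixed genes. Alternatives covered the block, the independence of days, background correction, normalization, detection filters, probes per gene, the variance model, array weights, thresholds, and leaving out each array and each time course. No slide is named in the files, so a slide block was not run.

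The fits were tested on simulated data built from the real means and residual SDs over 13572 genes, 200 of them changed. For a log2 change of 1, 98% were recovered in the mean effect, 79.5% for days 3 and 4, 87.5% for days 6 and 8, 50% for late minus early, 71% for the windows, 54% for day 2 and 50% for day 8. For a change of 0.5 the mean effect recovered 62.5% and days 3 and 4 recovered 14.5%. In a simulated list test the 1 shifted list was found and 0 of 21 others were called. Its noise was drawn independently for each gene, so it leaves out the correlation between members of a real list. It does not test the list calls against that correlation.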

Results

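Human embryonic stem cells of the line HuES6 were taken through directed cardiac differentiation in 2 time courses, and total RNA was hybridised to 27 bead arrays. Differentiation was induced in the first 24 hours with FGF2 at 10 ng/ml, BMP4 at 1 ng/ml and a CHIR compound at 1 µM, which activates WNT signalling. IWP-2 blocks Porcupine, the enzyme that acylates WNT proteins for secretion. It was added on days 2 and 3 in time course 1 and on days 1 and 2 in time course 2, and each time course had its own arm without inhibitor. The arms without inhibitor were sampled on days 0, 1, 2, 3, 4, 5, 6 and 8, giving 2 arrays per day, 1 from each time course. The inhibitor arms were sampled on days 3, 4, 5, 6 and 8, and in time course 2 also on day 2. Between 16424 and 19784 probes were detected per array, and mean signals ran from 293.1 to 349.5 except on 1 array, IWP-2 on day 8 of time course 2, with 225.2. The small number of arrays limits the precision. The labels do not say that the days of a series came from separate cultures, so the p-values measure the spread between these arrays, which may be technical in part.

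The first principal component held 38.1% of the variance and followed time. The second held 21.8% and set the inhibitor arms apart from the arms without inhibitor from day 4 on. Arrays of the same day and arm from the 2 time courses correlated across probes with r between 0.945 and 0.985.

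**Figure D1:**
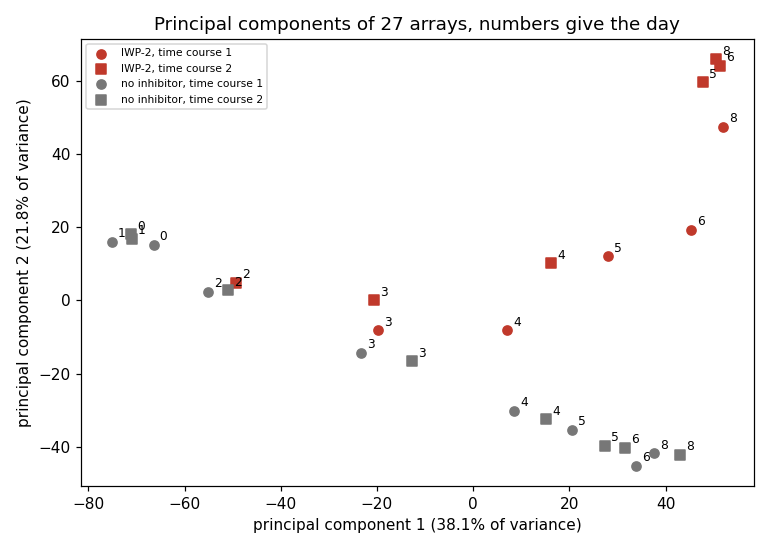
Principal components 1 and 2 of the 27 arrays, with the share of variance on each axis, colour for the arm, symbol for the time course and the day beside each point. Component 1, with 38.1% of the variance, follows time, and component 2, with 21.8%, parts the arms on later days.

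The induction step was examined by comparing day 2 without inhibitor with undifferentiated cells on day 0. Genes of the primitive streak and nascent mesoderm rose and genes of pluripotency fell. Of 19 measured members of the streak list, 13 rose and 0 fell. APLNR, the apelin receptor of early mesoderm, rose by 8.02 ± 0.62 (SE, 2 arrays against 2) on the log2 scale. MESP1, a regulator of cardiac mesoderm, rose by 7.25 ± 0.46, TBXT (brachyury) by 6.70 ± 0.34 and MIXL1 to at least 57.2-fold its level on day 0, where it was not above background. HAND1, a mesodermal transcription factor, was at least 167.9-fold higher. RSPO3, which codes for a secreted enhancer of WNT signalling, was at least 75.6-fold higher. Of 20 measured pluripotency genes, 15 fell and 0 rose, with SOX2 at -6.61 ± 0.72, LEFTY1 at -4.14 ± 0.34 and NANOG at -3.67 ± 0.23, while POU5F1 fell by 0.89 ± 0.22 on 1 of its probes and its other probe did not pass the test. The list of canonical WNT targets held 12 that rose among 20, among them LEF1 (at least 31.4-fold), MSX1 (5.81 ± 0.53) and CDX2 (at least 27.9-fold). AXIN2 differed by 0.33 ± 0.43 and did not pass. Paraxial mesoderm genes rose in 9 of 14 and posterior and lateral plate regulators in 8 of 12, with none lower past the test in either list. Of 19 stress and RNA quality genes 5 fell and 0 rose, FOS by 2.72 ± 0.51 and HSPH1 by 0.93 ± 0.24, with camera adjusted p = 0.025 and adjusted p = 0.056 with an estimated correlation. Adjusted over the list alone, 6 of these fell, 16 streak genes rose and 2 fell, 17 pluripotency genes fell and 14 WNT targets rose. In all, 1936 of 13572 genes passed an adjusted p of 0.05 in limma, 1042 higher and 894 lower. Without the time course block 1178 passed, 1060 without the day 2 array of time course 1, 1003 without that of time course 2, and 1237 without the day 0 array of time course 2.

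The state reached without inhibitor was described by comparing day 8 with day 0. It was marked by genes of fibroblasts and smooth muscle, posterior mesoderm, HOX genes and endothelium, while few contractile genes of cardiomyocytes passed the test. Of 33 measured contractile and calcium handling genes 6 rose and 2 fell, with camera, the set test, not calling the list (adjusted p = 0.20), and MYH6, the alpha cardiac myosin heavy chain, and NKX2-5, a cardiac transcription factor, were above background on neither day. Of 20 genes of the smooth muscle, fibroblast and epicardium list 14 rose and 1 fell. Other lists with a majority of risen genes were the posterior and lateral plate or extraembryonic mesoderm regulators (9 of 12), HOX genes (11 of 15), endothelial and blood genes (15 of 24), cardiac progenitor regulators (12 of 21), and trophoblast and amnion genes (9 of 14). Of the endoderm list 11 of 22 rose and 3 fell. ISL1 rose by 2.22 ± 0.82, KDR by 1.41 ± 0.37 and CDX2 to at least 5.00-fold its level on day 0. Of 20 pluripotency genes 19 fell, among them POU5F1 (-6.72 ± 0.22), SOX2 (at least 109.7-fold lower) and NANOG (at least 48.2-fold lower). Second probes fell less, at -0.57 for POU5F1 and -2.05 for NANOG. GAL, a neuropeptide gene, was at least 161-fold lower and ZIC2 fell by 7.29 ± 0.36. The proliferation list fell in 22 of 24 members, the glycolysis list in 13 of 17 and the list of FGF and ERK response genes in 10 of 14. Neuroectoderm genes fell in 8 of 12. Adjusted over the list alone, 12 HOX genes rose, and 24 proliferation genes and 12 FGF and ERK response genes fell. In all 5864 genes passed, 2945 higher and 2919 lower. Camera, with a preset correlation of 0.01, called 12 of the 22 lists. With an estimated correlation 2 of these calls held, pluripotency (adjusted p = 0.031) and the posterior mesoderm regulators (adjusted p = 0.034), and the adjusted p of the other called lists lay between 0.086 and 0.37.

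The effect during and just after the inhibitor was taken as the mean difference on days 3 and 4, with 4 arrays against 4. In the inhibitor comparisons, rose and fell mean higher and lower with IWP-2 than without it, and not a change with time. Canonical WNT targets, posterior mesoderm regulators and HOX genes fell together. Of 20 measured WNT targets 14 fell and 0 rose (16 fell when adjusted over the list alone), with a median log2 difference of -1.58, at -1.28 in time course 1 and -1.73 in time course 2. CDX2 fell by 5.13 ± 0.33, CDX1 by 4.00 ± 0.19, MSX1 by 3.92 ± 0.37, NKD1 by 2.49 ± 0.28, TBXT by 2.40 ± 0.24, LEF1 by 1.65 ± 0.23 and AXIN2 by 1.46 ± 0.30. With IWP-2, CDX2, CDX1 and TBXT lay below the lowest detected value on day 4 of time course 1 and days 3 and 4 of time course 2. Their falls may therefore be understated. CDX1 and CDX2 code for caudal-type homeobox factors, NKD1 and AXIN2 for feedback inhibitors of WNT signalling. Among the posterior and lateral plate or extraembryonic mesoderm regulators 8 of 12 fell and 2 rose (10 fell adjusted over the list alone). PRRX1 on this list was at least 36.9-fold lower on 1 probe, and a second fell by 2.03. CDX1, CDX2, MSX1 and MSX2 are on both this list and the WNT target list, so the lists are not separate evidence. Of 15 HOX genes 7 fell and 0 rose (11 fell adjusted over the list alone), HOXB8 at least 9.75-fold and HOXA2 by 2.19 ± 0.32. HOXB6 fell by 3.90 ± 0.43 on 1 probe and a second probe did not pass. The WNT ligand genes WNT5B and WNT3A fell by 2.39 ± 0.24 and 2.18 ± 0.27. RGS4, a regulator of G protein signalling, fell by 3.90 ± 0.41.

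Other genes were higher with IWP-2 than without it on days 3 and 4. LRRTM1 rose by 3.71 ± 0.67, CBLN2 by 3.25 ± 0.58, JAG1, a NOTCH ligand, by 2.92 ± 0.33, NETO1 by 2.81 ± 0.37, SHISA2 by 2.60 ± 0.57 and CCKBR by 2.54 ± 0.30. PGA3 and PGA5, which rose by 2.77 ± 0.48 and 2.54 ± 0.55, code for near-identical pepsinogens whose probes may share transcripts. Of 21 cardiac progenitor regulators 2 rose and 4 fell, 9 and 4 adjusted over the list alone and 5 and 4 with median scaling of the arrays, and camera did not call the list (adjusted p = 0.49). NKX2-6 rose by 1.87 ± 0.19 and MEF2C was at least 2.22-fold higher, while TBX3 fell by 2.40 ± 0.26 on 1 probe and a second did not pass. EOMES was higher with IWP-2 by 1.53 ± 0.31 and BMPER by 1.98 ± 0.27. With time EOMES fell in both arms. With IWP-2 it went from 9.99 and 10.2 on day 3 to 6.13 and 5.59 on day 4. Without inhibitor it went from 8.30 and 7.41 to 5.20 and 4.88. Of 33 contractile genes 2 rose, NEBL by 1.02 ± 0.24 and UNC45B by 1.73 ± 0.35 on 1 probe, while a second UNC45B probe did not pass. MYH6 differed by 1.60 ± 0.56 over both days and did not pass (adjusted p = 0.14), and neither did NKX2-5 (adjusted p = 0.076), which was not above background without inhibitor. The single days, with 1 array per arm and no test, lay apart: MYH6 with IWP-2 minus without was -0.96 in time course 1 and -2.22 in time course 2 on day 3, and 2.82 and 6.76 on day 4. With IWP-2 it was not above background on day 3 in time course 1. NKX2-5 was above background in neither arm on day 3, and on day 4 with IWP-2 alone, at 5.86 and 9.40. Of the smooth muscle, fibroblast and epicardium list 5 fell and 2 rose among 20, with 9 lower when adjusted over the list alone. In limma no member of the pluripotency, proliferation, glycolysis or trophoblast and amnion lists passed, and at an unadjusted p under 0.05 there were 5 of 20, 2 of 24, 2 of 17 and 1 of 14. With median scaling 1 pluripotency gene was higher.

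In all, 591 genes passed on days 3 and 4, 282 higher and 309 lower, all with the same sign in both time courses. The calls used both time courses together, so a shared sign is largely built in. Over all 13572 genes 63.69% had the same sign in both. With median scaling 727 passed, 69.2% of them higher against 47.7%, and with array weights 1109. Camera called 6 of 22 lists, and with an estimated correlation 3 held. These were WNT targets (adjusted p = 0.00036), posterior mesoderm regulators (adjusted p = 0.00036), which share members with the WNT targets, and HOX genes (adjusted p = 0.021). The calls of the fibroblast list (adjusted p = 0.15 with an estimated correlation), the contractile list (adjusted p = 0.76) and the streak list (adjusted p = 0.76) did not hold. The contractile call was also lost with median scaling (adjusted p = 0.30). The count moved to 350 without the time course block, to 296 or 297 without the day 3 or the day 4 inhibitor array of time course 2, and to 342 or 318 without the arrays of these days without inhibitor in time course 2.

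**Figure D2:**
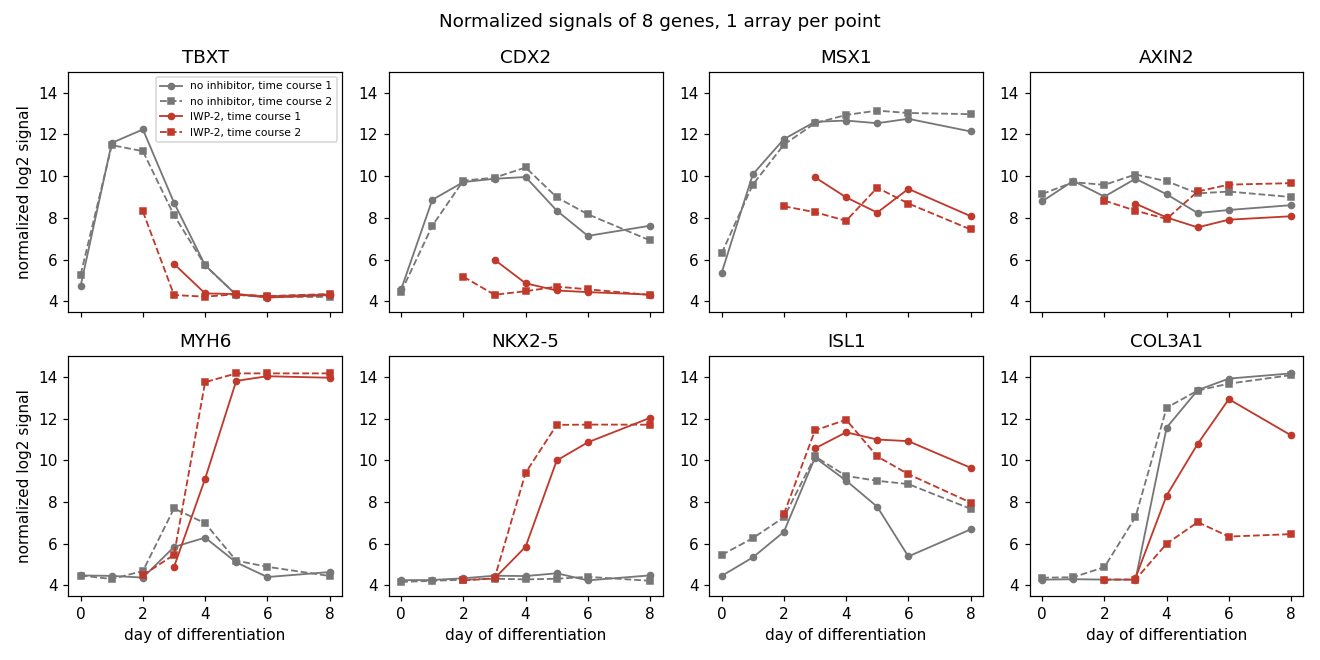
Normalized log2 signal of 8 genes against the day of differentiation, 1 array per point, with colour for the arm and line style for the time course. MYH6 stood at 13.7 on day 4 in time course 2 and at 9.1 in time course 1, and at 13.8 or above in both from day 5, against at most 7.7 without inhibitor.

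Days 6 and 8, the last sampled, gave the difference at the end of the series, with 4 arrays against 4. Nearly the whole list of contractile and calcium handling genes was higher with IWP-2, and genes of the posterior mesoderm, HOX genes and fibroblasts were lower. Of 33 measured contractile genes 31 rose and 0 fell, with a median log2 difference of 3.76, at 3.38 in time course 1 and 4.43 in time course 2. MYH6 rose by 9.48 ± 0.56, at 9.47 and 9.49 in the 2 time courses. In time course 2 with IWP-2 it reached the highest normalized value, 14.17, so the difference is bounded by the array's range. CKM, the muscle creatine kinase, was at least 125-fold higher, SMYD1, a muscle methyltransferase, at least 93.6-fold, and SMPX, MYOM1 and MYL3 rose by 6.80 ± 0.47, 6.75 ± 0.76 and 6.72 ± 0.88. EEF1A2, a translation elongation factor of muscle and nerve, rose by 6.34 ± 0.47. The regulators of cardiac progenitors were mixed, with 12 that rose and 4 that fell among 21. NKX2-5 was at least 110.2-fold higher, IRX4 at least 18.3-fold and NKX2-6 at least 6.65-fold, and MEF2C and GATA4 rose by 3.11 ± 0.33 and 1.92 ± 0.35. ISL1 was higher with IWP-2 by 2.31 ± 0.58, at 4.24 in time course 1 and 0.39 in time course 2. Its level with IWP-2 fell with time, from 11.3 and 11.9 on day 4 to 9.64 and 7.98 on day 8. HAND1, also near the top of the range, fell by 0.90 ± 0.22.

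Of 15 HOX genes 13 fell and 0 rose on days 6 and 8 (14 fell adjusted over the list alone), with HOXB8 at -6.52 ± 0.54 and HOXC8 at least 28.6-fold lower. Of the posterior and lateral plate regulators 9 of 12 fell, PITX1 by 7.25 ± 0.62 and PRRX1 at least 24.4-fold, and BMP2 rose by 4.01 ± 0.35. A second PRRX1 probe fell by 0.57 only. The smooth muscle, fibroblast and epicardium list had 13 that fell and 5 that rose among 20. DCN (decorin) fell by 7.53 ± 0.67, POSTN (periostin) at least 38.2-fold and LUM (lumican) by 5.06 ± 0.79. Other DCN probes fell by 5.80 and 2.82. COL3A1 fell by 4.73 ± 1.13, at -1.98 in time course 1 and -7.48 in time course 2. Of 22 endoderm genes 8 fell, among them AFP by 3.34 ± 0.30 and FGA by 2.98 ± 0.17, and of 24 endothelial and blood genes 5 fell. With median scaling 12 endoderm and 8 endothelial genes fell. The WNT target list had no common direction, with 3 that rose and 6 that fell among 20. MSX1 still differed by -4.32 ± 0.37, while the AXIN2 difference of 0.00 ± 0.30 (adjusted p of 1) averaged -0.50 in time course 1 and 0.50 in time course 2.

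Glycolysis, FGF and ERK response and proliferation genes also differed on days 6 and 8. Of 17 glycolysis genes 15 rose and 1 fell, with a median of 1.56, GPI by 2.55 ± 0.19 and ALDOA by 2.16 ± 0.23. The reference genes GAPDH and PGK1, also glycolytic enzymes, rose by 1.17 ± 0.13 and 1.74 ± 0.19. Of 14 FGF and ERK response genes 7 rose and 0 fell (8 adjusted over the list alone), with ETV5 at 4.18 ± 0.40 and DUSP6 at 3.41 ± 0.43. Second probes rose less, at 1.91 for ETV5 and 2.11 for DUSP6. Of 14 BMP and TGF-beta response genes 6 rose and 1 fell. Of 24 proliferation genes 18 fell and 0 rose (20 adjusted over the list alone), TOP2A by 2.08 ± 0.38 and CDK1 by 1.81 ± 0.36. WNT2 rose by 5.22 ± 0.53 and FRZB, a secreted WNT antagonist, fell by 5.43 ± 0.35.

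In all, 4746 genes passed on days 6 and 8, 2301 higher and 2445 lower, 812 and 851 of them by at least 2-fold. Camera called 11 lists, and with an estimated correlation 0 of them held, and 6 of the 22 lists had an unadjusted p under 0.05. Fry, which tests a list against no change and not against the other genes, called 16, a different question where many genes changed. The adjusted p with an estimated correlation was 0.078 for the contractile list and for the posterior regulators, 0.10 for HOX genes and glycolysis, 0.12 for cardiac progenitor regulators, 0.14 for FGF and ERK response, 0.34 for endoderm and for BMP and TGF-beta response, 0.35 for proliferation and for the fibroblast list, and 0.50 for endothelial and blood genes. The endothelial and blood call was also lost without the dim array (adjusted p = 0.32) and with median scaling (adjusted p = 0.19), and the fibroblast call with median scaling (adjusted p = 0.063). With this scaling in place of quantile normalization the median of all genes lay at -0.17 and 28.5% of the called genes were higher, against 48.5%. With the differences in each time course averaged to 1 value first, 1633 genes passed.

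**Figure D3:**
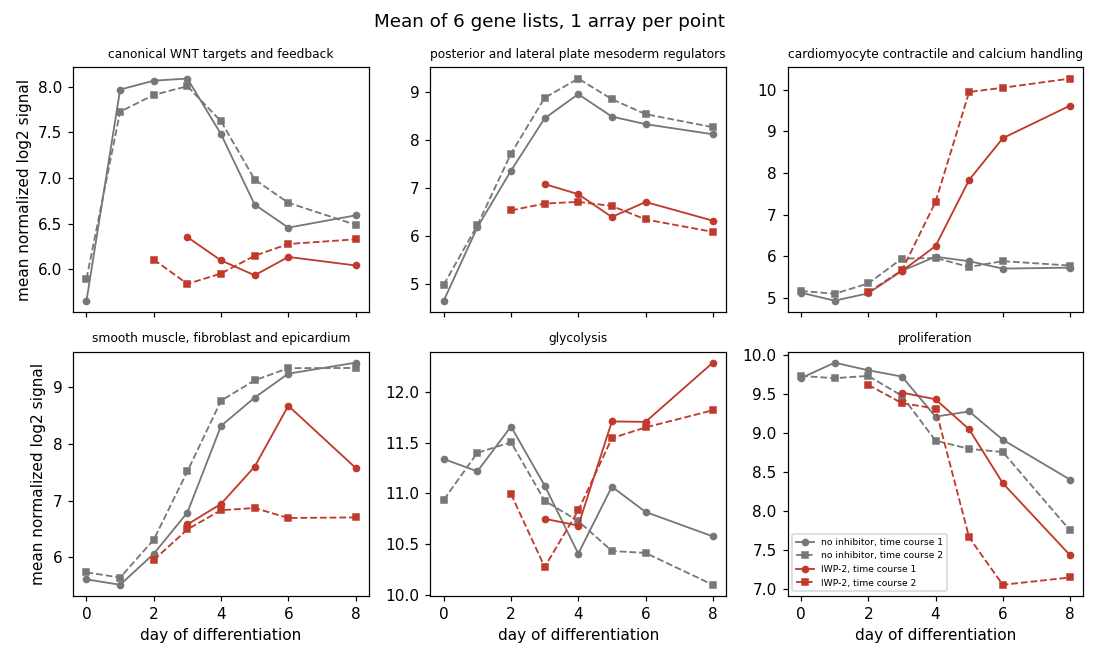
Mean normalized log2 signal of the measured members of 6 gene lists against the day of differentiation, 1 array per point. The contractile list separates between the arms after day 3, and the median difference of its members on days 6 and 8 was 3.76.

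**Figure D4:**
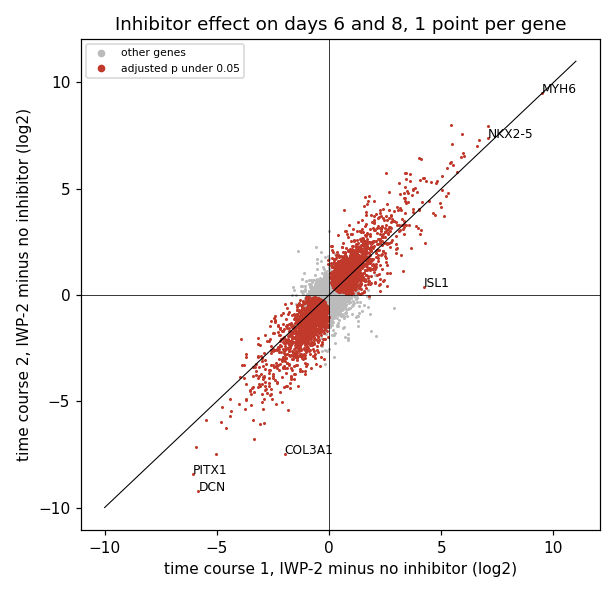
Inhibitor effect on days 6 and 8 in time course 1 (horizontal axis) and time course 2 (vertical axis), in log2, 1 point per gene, with genes past an adjusted p of 0.05 in red and a line of equal effects. Across 13572 genes Pearson's r was 0.838, and ISL1 and COL3A1 lie off the line.

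Whether the inhibitor effect changed between the stages was tested as the difference between the effect on days 6 and 8 and that on days 3 and 4. Of 33 contractile genes 30 had a positive difference past the test and 0 a negative one. Camera called the list, and with an estimated correlation the call did not hold (adjusted p = 0.064). Among the largest gains were MYH6 at 7.88 ± 0.79, MYL3 at 6.57 ± 1.24, MYOM1 at 6.52 ± 1.07 and TNNC1 at 6.47 ± 0.63. With IWP-2 on days 6 and 8 of time course 2 MYH6 was at the highest normalized value, so its gain may be understated. Without inhibitor MYH6 was above background on 1 of the 4 arrays of days 6 and 8 and CKM and PPP1R14C on none, and VCAM1 on none of days 3 and 4. CKM, PPP1R14C and VCAM1 also passed, but the size of their differences was not measured, and for VCAM1 the sign is not established either. Among WNT targets the difference was 1.46 ± 0.43 for AXIN2 and 1.17 ± 0.32 for LEF1. CDX1 (2.95 ± 0.27), TBXT (2.42 ± 0.34) and CDX2 (2.08 ± 0.46) passed as well, but with IWP-2 none of them was above background on days 6 and 8. Their later loss is therefore only a lower bound, and these values do not show that it was smaller than the earlier one. TBXT was above background in neither arm from day 5 on. For MSX1 the difference was -0.40 ± 0.53 and did not pass. PITX1, PRPH and FRZB moved further down, by -5.64 ± 0.88, -5.36 ± 0.80 and -4.36 ± 0.49, with PITX1 and PRPH above background on 2 of the 4 inhibitor arrays of days 6 and 8. DCN and POSTN also passed, but with IWP-2 neither was above background on days 3 and 4, nor POSTN on days 6 and 8. Neither the size nor the sign of their change between the stages is therefore established. In all 2477 genes passed, 1233 with a positive and 1244 with a negative difference, 1461 without the time course block and 3842 with median scaling, where 18.1% were positive against 49.8%.

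Over days 3 to 8 together, with 10 arrays against 10, 4968 genes passed, 2497 higher and 2471 lower. Of these 4952 had the same sign in both time courses, which the joint test largely builds in, against 71.32% of all 13572 genes. With 1 value per time course 1227 passed. The effects of the 2 time courses share no array. Across genes, which are not independent replicates, their Pearson correlation was 0.831 and Spearman's rho 0.658 for the mean effect, 0.671 and 0.438 for days 3 and 4, and 0.838 and 0.683 for days 6 and 8. Within time course 1 alone, paired by day, 172 genes passed for the mean effect, 2 for days 3 and 4 and 1808 for days 6 and 8. Within time course 2 alone the counts were 982, 107 and 3042.

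The time courses used different inhibitor windows, so window and time course cannot be told apart. IWP-2 was given on days 1 and 2 in time course 2 and on days 2 and 3 in time course 1. The test took the difference between the time courses, 2 minus 1, with IWP-2 on days 3 to 8. It subtracted the same difference without inhibitor, taken over days 0 to 8. This interaction passed for 60 genes, 12 positive and 48 negative. COL3A1 (-4.04 ± 0.83), the mesenchymal transcription factor gene SNAI2 (-2.80 ± 0.46), HLX (-2.41 ± 0.26) and the imprinted transcript H19 (-2.38 ± 0.30) fell further in time course 2, and MYH7, the beta cardiac myosin heavy chain, rose further (2.07 ± 0.42), though without inhibitor it was above background on no array of days 3 to 8, so the size is uncertain. A second HLX probe did not pass. NKX2-5 and ISL1 did not pass, with adjusted p of 0.18 and 0.15. For MYH6, at the highest normalized value on days 5, 6 and 8 with IWP-2 in time course 2, a further rise there could not be measured. The count was unstable, between 4 and 357 when 1 array was left out, 258 with median scaling, where 6.2% were positive against 20.0%, and 136 with array weights. In a separate fit to the daily differences between the arms on days 3 to 8 alone, 15 genes passed. Other groupings of these daily differences gave counts as large as 15 or larger. The largest came from comparing the time courses on days 5, 6 and 8 alone. On day 2 the inhibitor was sampled in time course 2 only, with 1 array per arm and no test. TBXT stood at 8.31 with IWP-2 and 11.2 without, CDX2 at 5.18 and 9.79, and SOX2 at 8.76 and 5.62.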

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

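In this part the tests on the SDs without day 8, on the transcripts left in time course 1 and on the glycolysis median in time course 1 were chosen after the results were seen, as were the margin for the distance between days, the splits that part every pair and those balanced within each time course.

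The inhibitor effect differed between the stages for 2477 genes, by a test of the difference itself. In 35 splits of the same 8 differences 1, the real one, reached its count of 2479, and limma called 0 genes in the highest other. That is a share under 0.05 of these free groupings, which mix the time courses. Of them 18 are balanced within each time course, too few for a share under 0.05, so chance is not excluded. At an unadjusted p under 0.05 the real one gave 4578 genes and the highest other of the 18 gave 1678. The positive differences were MYH6 7.88, CKM 7.66, PPP1R14C 6.61, MYL3 6.57, MYOM1 6.52, TNNC1 6.47, SMPX 6.40, VCAM1 6.13, NKX2-5 5.64, CDX1 2.95, MESP1 2.59, TBXT 2.42, CDX2 2.08, AXIN2 1.46, LEF1 1.17 and TBX5 0.97. A second TBX5 probe did not pass. The negative ones were PITX1 -5.64, PRPH -5.36, DCN -5.23, POSTN -5.02, MFAP4 -4.59, LY6H -4.56, SLN -4.54, FRZB -4.36 and EOMES -1.51. For many of these an arm was not above background on any array of a stage, so the value passed a test but the size was not measured, and for some the sign stays open. This holds without inhibitor for NKX2-5 and TBX5 in both stages, SMPX and VCAM1 on days 3 and 4, and CKM and PPP1R14C on days 6 and 8. With the inhibitor it holds for POSTN in both stages, PPP1R14C, DCN and SLN on days 3 and 4, and CDX1 and CDX2 on days 6 and 8. Where the inhibitor arm was not above background, the effect may lie lower than measured, and where the arm without inhibitor was not, higher. The sign of the stage difference is therefore not established for CDX1, CDX2, DCN, SLN and POSTN, nor for NKX2-5, TBX5, SMPX and VCAM1. MYH6 was at the highest normalized value with the inhibitor on days 6 and 8 of time course 2, so its size is bounded as well. TBXT and EOMES were above background in neither arm on days 6 and 8, so their values only mark the end of an earlier effect.

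For the mean effect 1 of 100 splits of the 20 arrays reached the real count of 4375, and the highest other gave 2388. For days 3 and 4, 1 of 35 splits reached 330, and the highest other gave 234. That other split parts time course 1 from time course 2, a batch, and the effect in the report has the time course as a block. For days 6 and 8, 1 of 35 splits reached 3958, and the highest other gave 1. The real split alone reached its count in each of these 3, a share under 0.05. These splits exchange arrays freely, however, and break the pairing of the arms. Arrays of the same time course and day pair the arms, and the highest other splits parted 8 of 10 pairs for the mean effect and 0 of 4 for the other comparisons. Of the splits that part every pair, 100 of 512 were run for the mean effect, where the highest other gave 1205, and all 8 for days 3 and 4 and for days 6 and 8, where limma called 0 genes in the highest other. At an unadjusted p under 0.05 these gave at most 1128 on days 3 and 4 and 1251 on days 6 and 8, against 2703 and 5496 in the real ones. With 8 splits no share under 0.05 can be had, so chance is not excluded for days 3 and 4 or for days 6 and 8. For the mean effect 1 of the 100 run, the real one, reached 4375. Its 10 pairs are days of 2 time courses, not known to be separate cultures, so chance is not excluded there either. The splits' models hold the compared arrays alone, with time course and day as terms, so their counts differ from the report's.

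Between the windows 60 genes differed by the interaction test, which takes the arm without inhibitor over days 0 to 8. The largest positive differences, time course 2 minus time course 1, were KLHL14 2.35, MYH7 2.07, NMRK2 2.01, TNNC2 1.91, CACNA1G 1.67, KLHL2 1.14, SLC25A34 0.99 and RANGRF 0.94. The negative ones were COL3A1 -4.04, SNAI2 -2.80, CCDC3 -2.69, HLX -2.41, H19 -2.38, CDC42EP5 -1.97, NOX4 -1.93 and EFEMP1 -1.88. Second probes of NMRK2, HLX and NOX4 did not pass. Without inhibitor MYH7 and TNNC2 were not above background on days 3 to 8 in either time course, KLHL14 and CACNA1G not in time course 2 and NMRK2 not in time course 1, and SLC25A34 was above background in neither arm of time course 1, so the size of these differences is uncertain. Of 100 splits of the 10 daily differences, 5 gave at least the real count of 15, and the highest other gave 626, so over free groupings chance cannot be excluded for the count. The split with 626 is the real one with day 4 of time course 1 and day 3 of time course 2 exchanged. With day as a term, days 3 and 4 then carry no information on the split. It compares the time courses on days 5, 6 and 8 alone, so it is part of the real comparison and not a grouping by chance. Without either inhibitor array of day 3 the count was 357, and 223 without either of day 4. Of the 16 splits that part the time courses on every day, too few for a share under 0.05, the real one gave 15 and limma called 0 genes in the highest other (2704 and at most 1650 at an unadjusted p under 0.05).

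Effects were also larger in time course 2, with a ratio of the SDs over genes of 1.43, and the dim array is argued against as the cause, since without day 8 the ratio was 1.489. Whether cells that did not respond in time course 1 account for this was examined on abundant genes. The window genes COL3A1 and H19 kept a median 32.7% of their linear signal there, against 11.59% for 26 others. The window test had set these 2 apart for falling less in time course 1, on the same arrays. Their higher share is therefore built in, and the comparison cannot argue against such cells. The 26 others ran from 2.638% (10th percentile) to 24.5% (90th), so the share left was not common to them. RELN and FLRT3, among the 26, kept as much as these 2, and the other window genes did not enter this comparison. A schedule about 1 day ahead in time course 2 may contribute, as its inhibitor array was nearer to the next day of time course 1 on 2 of 3 days, but this does not decide, since without inhibitor it was on 1 of 3, and by at least 5% on 1 in each arm. Each window was used in 1 time course, so the window, a biological difference of the design, cannot be told apart from the run.

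Glycolysis genes were higher with the inhibitor on days 6 and 8 in 15 of 17. The tables argue against quantile normalization as the source, since 14 were called with median scaling, against the dim array, since 15 were called without it, and against time course 2 alone, since the median in time course 1 was 1.355. The inhibitor, through the cells it leaves, stays as a hypothesis, and a shift in the mix of cell types was not tested and may account for it as well.

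Probes without a single named gene were not part of the comparisons. Of 5498 that were detected, 1049 differed on days 6 and 8, 503 higher and 546 lower with the inhibitor.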

How the results depend on the processing

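The gene lists under median scaling and without the dim array were alternatives chosen after seeing the data. No called gene named here changed sign under any alternative. Of the named genes' values under the alternatives, 21541 kept sign and side of the threshold, 1648 fell short of it, 39 came past it and 88, called in neither fit, changed sign. Stricter thresholds, the test of every probe and leaving out an array outside a comparison leave a named gene's difference as it was. They could not change its sign, so these counts overstate how far the signs were tested. No slide is named in the files, so a slide block was not run. The cause of the changes below was not tested, except that stricter thresholds and single time courses pass fewer genes by construction. Without the replicate block the counts were 350 for days 3 and 4 (591 with it), 1461 for late minus early (2477) and 1178 for day 2 (1936), and the block moved no other count by over 1.5 times. The window difference could not be fitted without it, with random blocks or within 1 time course. With 1 value per time course 1227 genes passed for the mean effect and 1633 for days 6 and 8. At an adjusted p of 0.01 the counts were 3286 for the mean effect, 273 for days 3 and 4, 1165 for late minus early, 4 for the windows and 974 for day 2. With at least 2-fold they were 809, 305, 1663 (days 6 and 8), 1332, 978 (day 2) and 3119 (day 8). Array weights gave 1109 for days 3 and 4 and 136 for the windows. Median scaling gave 3842 for late minus early and 258 for the windows. With it the median of all genes was 0.12 on days 3 and 4 (0.02 with quantile normalization), -0.17 on days 6 and 8 (-0.02), -0.31 for late minus early (-0.05) and -0.12 for the windows (-0.01). The positive share of calls went from 47.7% to 69.2%, from 48.5% to 28.5%, from 49.8% to 18.1% and from 20.0% to 6.2%. The windows gave 32 genes without background correction, 31 with the authors' processed values and 16 without the detection filter.

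Leaving out 1 array gave 4318 to 5163 genes for the mean effect, 296 to 639 for days 3 and 4, 3535 to 4874 for days 6 and 8, 1682 to 2790 for late minus early, 4 to 357 for the windows, 1003 to 1991 for day 2 and 4478 to 5988 for day 8. A group then left with 1 array is assumed to vary like the other groups. The windows gave 4 without either day 5 inhibitor array, 5 without either of day 6, 32 without either of day 8, 223 without either of day 4 and 357 without either of day 3. They gave 94 without either array of day 0, 33 without either of day 8 without inhibitor, and 15 to 24 without either of days 1 to 6 without inhibitor. Day 2 fell to 1003 without its array of time course 2. Within 1 time course the counts were 172 and 982 (mean), 2 and 107 (days 3 and 4), 1808 and 3042 (days 6 and 8), and 182 and 736 (late minus early), each time course 1 first. The lists called were 4 and 8 on days 3 and 4, and 8 and 11 on days 6 and 8. With an estimated correlation camera called 3 lists on days 3 and 4, 0 on days 6 and 8 and 2 on day 8. The dim array left out, 6, 10 and 12 lists were called, and with median scaling 5, 9 and 12. The correlation between time courses without background correction, with the authors' values and without the filter was 0.838, 0.822 and 0.822 for the mean effect (0.838 with probes on at least 6 arrays), 0.710, 0.628 and 0.639 for days 3 and 4 (0.689), and 0.847, 0.831 and 0.831 for days 6 and 8. Signal over background limits genes at the floor, whose folds are bounds.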

Other observations

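The smooth muscle, fibroblast and epicardium list with the inhibitor had a mean log2 signal of 8.68 on day 6 of time course 1, against 7.60 on day 5 and 7.58 on day 8, and of 6.69 on day 6 of time course 2. Without inhibitor MYH6 was above background on days 3, 4 and 5 in both time courses, at 5.85 and 7.69 on day 3 and 6.29 and 6.98 on day 4, and not on days 0 and 8. ISL1 without inhibitor was at 10.1 and 10.2 on day 3, and on day 6 it stood at 5.39 in time course 1 and 8.86 in time course 2. SOX2, at 11.96 and 11.15 on day 0, was at 8.29 with the inhibitor on day 3 of time course 2 and not above background on the other arrays of that day. The difference of SOX2 on days 3 and 4, 1.78 ± 0.51, did not pass (adjusted p = 0.061).

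Of the lists not described above, 3 of 14 paraxial mesoderm genes rose on days 3 and 4 and 1 fell, 4 of 14 BMP and TGF-beta response genes rose and 1 fell, and camera called neither. On days 6 and 8 the NOTCH list had 5 that rose and 4 that fell among 17, the cholesterol synthesis list 1 and 2 among 13, the stress and RNA quality list 3 and 3 among 19, the neuroectoderm list 3 and 0 among 12, and the WNT ligand, receptor and antagonist list 6 and 7 among 29. With median scaling of the arrays the NOTCH list had 2 and 5, the cholesterol list 1 and 5, the stress list 3 and 4, the neuroectoderm list 3 and 1, and the WNT ligand list 3 and 8. The pluripotency list had 1 and 7 among 20, the streak list 5 and 2 among 19, the paraxial mesoderm list 2 and 1 among 14 and the reference genes 4 and 3 among 12. The trophoblast and amnion list had 3 that fell among 14, and 5 with median scaling. Camera called none of these.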
